A study of Mus musculus with 24 samples.

How the data were processed

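Chromatin immunoprecipitation followed by sequencing was carried out in primary mouse embryonic fibroblasts (MEFs) of both sexes, either wild type (WT) or lacking the deacetylase SIRT7 (KO). Per the labels, antibodies against the histone variant H2AX and against its phosphorylated form gH2AX were used beside input chromatin, and all cells had received 5 Gy of X-rays followed by 30 min of recovery. The 24 libraries fell into 12 groups of 2, each combination of antibody or input, sex and genotype being a group. The labels do not state that the 2 libraries of a group came from separate cultures, so every p-value measures only the spread between these samples. A difference between KO and WT within a sex can thus not be told from a difference between the cultures or animals used.

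The deposited values were raw read counts per 100 kb bin of the mouse genome, with 1 column per library and 27268 bins in the table. Per the submitters' processing notes, FastQC 0.11.3, Trimmomatic 0.36, Bowtie2 2.2.9, SAMtools 0.1.19, deepTools 2.4.2 and MACS2 2.2.7.1 were used with genome build mm10. Neither the labels nor the file state how duplicates or reads with several alignments were handled, so counts over repeats cannot be assigned to a locus. The table also held 24 columns of libraries that match no labelled sample, and these were left out of every step. Totals ranged from 84.5 M to 212 M reads for gH2AX, from 66.9 M to 250 M for H2AX and from 92.4 M to 269 M for input (M, 1e6), with a median of 2340 to 9362 reads per bin. Replicates differed by more than counting error in all 12 groups, with a chi-square per degree of freedom of 2.58 to 3.55.

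Counts were fitted in R 4.3.3 with edgeR 4.0.16. Bins on chromosomes 1 to 19 and X (26350) were kept where filterByExpr passed them, which left 25702 bins for gH2AX and 25703 for H2AX and input. TMM factors were computed on autosomal bins only. Each antibody was fitted with a mean per sex and genotype group, and the quasi-likelihood F test (two-sided) was used for KO against WT within each sex, for the difference of the KO effects between the sexes, for KO against WT averaged over the sexes and for female against male. Ratios between antibodies, or of antibody to input, came from a fit of all 24 libraries. Adjusted p-values are Benjamini-Hochberg values over the bins tested, and a bin was called at an adjusted p under 0.05. Standard errors (SE) of bins and chromosomes are the log2 change divided by the square root of F. The median biological coefficient of variation was 2.12% for gH2AX, 2.13% for H2AX and 1.86% for input.

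Chromosome X was tested as a unit against the autosomes, with reads summed over each of 20 chromosomes, library sizes set to the autosomal sum and the same edgeR test, adjusted over the 20 chromosomes. In 100 simulated data sets of the female gH2AX comparison, the dispersion estimated by edgeR returned p-values near 1 for 8.65% of the 20 chromosomes. The dispersion was therefore fixed at 0.001. At an unadjusted p under 0.05, this setting found an X shift of 0.02 (log2) in 99% of the simulated sets at 5.53% false positives. The estimated dispersion found it in 98% at 1.74%. Calls on the real counts used adjusted p-values, for which these shares were not measured. The value of 0.001 was chosen on the simulation, but after p-values from both settings had been seen on the real counts. An exact two-sided permutation test of the log2 ratio of X to autosomal reads per library was run beside it.

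The bin test was also tested on simulated counts with known changes. For gH2AX in females (25702 bins), 4% of the bins changed by 1.05-fold were called, 54% at 1.1-fold and 100% at 1.2-fold, and 3.73% of calls were false. The shares called at 1.1-fold were 40% for gH2AX in males (25702 bins), 62% for H2AX in females and 58% for H2AX in males (25703 bins each). The share of false calls was 4.00% for gH2AX in males, 8.22% for H2AX in females, 7.14% for H2AX in males and 6.99% for input in females, above the 5% aimed at in the last 3.

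A total of 46 lists of bins was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. The lists held 21 sets of genes, the 20 chromosomes, chromosome ends, the chromosomes with nucleolar organisers and bins rich or poor in genes. A bin belonged to a gene list when it overlapped a listed gene of the RefSeq annotation of GRCm38. Values for a single gene are those of the 100 kb bin that holds most of its body (the first bin it fills, for longer genes) and are not specific to the gene.

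Regions were named by rule. Called bins were merged with called neighbours of the same direction, the 8 regions with the most bins per direction were taken, and their position and up to 3 protein-coding genes were given. For KO against WT within a sex and a single antibody or input, only called bins whose 2 groups did not overlap between libraries were merged. The other comparisons had no such requirement. For ratios to input, the 8 highest and 8 lowest called bins were taken. From the gene lists, the members with the largest called changes were named, and all members of the X inactivation centre, X escape, inactive-X structural and sirtuin lists could be named.

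The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Those alternatives were RLE factors, TMM with X included, no filter on low counts, a window on input depth (0.5 to 1.5 of the median), subtraction of the input change, a replicate number shared between groups as a block, joint fits, DESeq2 1.42.0, limma or the median of bins for chromosomes, and leaving out each library. Where a group was left with 1 library, that library was assumed to vary like the others. Removal of the trend of each library on bin enrichment, removal of bins called in input and the dispersion setting were added after the data had been seen. The trend was a spline on gH2AX over input as measured in the other sex, fitted on autosomal bins and held level at the extremes of enrichment.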

Results

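The libraries profiled H2AX, gH2AX and input DNA in irradiated female and male MEFs with or without SIRT7, a NAD-dependent deacetylase. gH2AX is the form of H2AX phosphorylated around DNA double-strand breaks. Each of the 12 groups held 2 libraries of 66.9 M to 269 M reads, and all log2 changes are given with their SE and as KO relative to WT unless stated otherwise. No labelled sample was unirradiated, and the columns that match no labelled sample were not used. Levels induced by X-rays could thus not be separated from those present before.

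The labels of sex and genotype were checked first. The log2 ratio of X to autosomal reads in input was -3.99 in both female groups and -4.85 and -4.85 in male KO and WT, and chromosome Y held 0.0913% of the reads of female KO input against 1.58% in male KO input. The bin that holds Sirt7 (11: 120600001 to 120700000) did not differ in input, and a 100 kb bin cannot show a deletion of an exon. Its neighbour (11: 120500001 to 120600000, P4hb, Gcgr, Mcrip1) was higher in KO in input, H2AX and gH2AX of both sexes. In input it had 64.1 ± 1.15 (SD, n = 2) normalised counts per M reads (CPM) in female KO against 37.1 ± 0.118 in WT, and 64.3 ± 0.909 in male KO against 35.4 ± 0.429. The log2 changes there were 0.79 and 0.86 in input, 0.90 and 0.83 for H2AX, and 0.70 and 0.91 for gH2AX, in females and males. The ratio of gH2AX to H2AX there was lower in KO females (-0.21, adjusted p = 0.00586) and did not pass in males (0.09, adjusted p = 0.118). The 2 changes differed by -0.29 (adjusted p = 2.86e-04). The libraries labelled KO could thus be told from those labelled WT in each sex, although not by loss of the targeted gene.

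Where each mark lay along the genome was asked by comparing it with input over all 4 sex and genotype groups. gH2AX and H2AX were both enriched in gene-rich bins. In the 685 bins with 5 or more protein-coding genes, the median log2 ratio to input was 0.35 for gH2AX and 0.35 for H2AX, and in the 14378 bins without a gene midpoint it was -0.09 and -0.11. Bins of ribosomal protein genes carried more of both marks (median 0.32 and 0.31, with 68 of 72 bins higher for gH2AX and none lower). Olfactory receptor bins had less gH2AX (median -0.16, 275 of 345 bins lower), as had bins of vomeronasal receptors (-0.13, 180 of 218 lower). The adjusted p-values were 9.65e-20, 3.64e-09 and 2.41e-08, and 0.00568, 0.0104 and 0.0222 with an estimated correlation.

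The highest gH2AX ratio to input was 3.38 ± 0.01 (log2, 10.4-fold), at 17: 39800001 to 39900000. The annotation places Rn18s-rs5, a sequence related to 18S ribosomal RNA, in this bin. H2AX itself was lower than input there (-0.26). The next bins were 11: 109000001 to 109100000 (2.03, no protein-coding gene), 16: 11100001 to 11200000 (1.70, Zc3h7a, Txndc11, Rsl1d1), 16: 57300001 to 57400000 (1.68, Cmss1, Filip1l, Tmem30c), 3: 5800001 to 5900000 (1.66, no protein-coding gene), 5: 146200001 to 146300000 (1.53, Cdk8, Rnf6), 9: 123400001 to 123500000 (1.24, Lars2, Limd1) and 16: 17200001 to 17300000 (Hic2, Tmem191c, Pi4ka). The lowest were 1: 24600001 to 24700000 (-1.87, Lmbrd1), X: 126700001 to 126800000 (-0.81) and 6: 103600001 to 103700000 (-0.55, Chl1). The bin of Chl1 held a mean of 177039 reads per library, 0.12% of all reads. Genes named for the highest and lowest bins give their position only. Whether reads of repeats gathered in these bins was not tested. H2AX was highest at 7: 90400001 to 90500000 (1.59, Dlg2, Sytl2, Tmem126b) and 14: 45800001 to 45900000 (1.38), and lowest at the bin of Lmbrd1 (-3.31). Of 25703 bins, 22271 differed from input for gH2AX (10663 higher, 11608 lower) and 22985 for H2AX (11546 higher, 11439 lower). Across these bins, which are not independent replicates, the ratios of the 2 marks correlated with r = 0.85 and rho = 0.86. Both ratios were taken to the same input libraries, which can raise this correlation by itself.

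In males, the gH2AX profile differed between KO and WT over much of the genome, by small amounts. The widest stretches that rose were 2: 29400001 to 33500000 (41 bins, Ralgps1, Hmcn2, Garnl3), where the leading bin changed by 0.24 ± 0.03, and 17: 23500001 to 27200000 (37 bins, Ergic1, Abca17, Lmf1, 0.23 ± 0.03). Others were 8: 121100001 to 122900000 (Zfp469, Banp, Cbfa2t3, 0.26 ± 0.04) and 7: 79100001 to 80700000 (0.23 ± 0.04), which holds Blm, the helicase lost in Bloom syndrome. The widest that fell were 2: 97600001 to 101500000 (39 bins, Lrrc4c, -0.23 ± 0.02), 2: 86800001 to 90000000 (32 bins of olfactory receptors, Olfr1234, Olfr1258, Olfr1109, -0.22 ± 0.04), 5: 58800001 to 61700000 (29 bins without protein-coding genes, -0.26 ± 0.04), 14: 106800001 to 109700000 (29 bins, Slitrk1, -0.24 ± 0.04) and 7: 84900001 to 87200000 (Folh1, Vmn2r79, Vmn2r78, -0.27 ± 0.04). The value given for the Lrrc4c stretch is that of the bin at 2: 98600001 to 98700000. This bin held 5.23% of all reads, so its value need not stand for the stretch. In all, 11481 of 25702 bins passed (5765 higher, 5716 lower), with a median size of 0.13, and 16 of them exceeded 0.5. Leaving out male KO replicate 2 gave 7510 bins and leaving out male WT replicate 2 gave 7000. Subtraction of the input change gave 5027 bins. Removal of each library's trend on enrichment left 583 bins, 404 of them shared, with 0.15 and 0.13 in the leading bins at Zfp469 and Blm.

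By gene group, ribosomal protein bins rose in KO males (47 of 72 higher, none lower, 48 adjusted over the list alone, median 0.11, adjusted p = 6.41e-12, or 0.0607 with an estimated correlation). Examples were the bins of Rps3 (0.24) and Rpl13a (0.22). Bins of the double-strand break response rose in 18 of 31 cases and fell in none (19 adjusted over the list alone, median 0.10, adjusted p = 1.34e-05, or 0.0564 with an estimated correlation). They included Rnf8 (0.21), a ubiquitin ligase recruited to breaks, Rad50 (0.17), a subunit of the MRN complex, Chek2 (0.17), a checkpoint kinase, and Brca1 (0.16). Zinc finger genes had 151 of 351 bins higher and 34 lower (194 adjusted over the list alone, 0.07, adjusted p = 3.07e-06, or 0.0564 with an estimated correlation), led by Zfp276 (0.25). Of the p53 target bins 11 of 25 rose and none fell (13 adjusted over the list alone, 0.07, adjusted p = 0.00996, or 0.131 with an estimated correlation), among them Sesn2 (0.18), a stress-response gene, Phlda3 (0.17), Btg2 (0.14) and Cdkn1a (0.14), which encodes the cell-cycle inhibitor p21. Of the bins listed for replication-dependent histones 8 of 12 rose (8 adjusted over the list alone, 0.12, adjusted p = 0.00115, or 0.188 with an estimated correlation), the largest being that of H1f8 (0.22), an oocyte linker histone that is not replication-dependent. Of the sirtuin bins 4 of 7 rose (4 adjusted over the list alone, 0.12, adjusted p = 0.0354, or 0.191 with an estimated correlation): Sirt2 (0.16), Sirt4 (0.14), Sirt7 (0.13) and Sirt6 (0.12). Of all bins with 1, 2, 3 to 4 and 5 or more protein-coding genes, 31.2%, 40.4%, 51.5% and 62.2% rose in KO males. In the same order, 11.1%, 8.2%, 9.8% and 12.8% fell. These lists were compared with all other bins and not with bins of like gene number, so their rise need not be particular to them.

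Olfactory receptor bins fell in KO males (213 of 345 lower, 13 higher, 237 adjusted over the list alone, median -0.12, adjusted p = 3.94e-14, and 0.0413 with an estimated correlation), with -0.29 at Olfr1303. This bin was also lower in H2AX (-0.29) and in input (-0.19) of KO males. Vomeronasal receptor bins fell likewise (122 of 218 lower, 4 higher, 133 adjusted over the list alone, -0.11, adjusted p = 8.80e-13, and 0.0439 with an estimated correlation), with -0.28 at Vmn2r113. Bins of long genes at fragile sites fell more often than they rose (93 lower, 22 higher of 314, 106 adjusted over the list alone, -0.05, adjusted p = 0.00175, or 0.202 with an estimated correlation). Lrp1b (-0.21), Dmd (-0.15) and Csmd1 (-0.13) fell and Wwox (0.13) rose. Among cell-type lists, 7 of 19 haematopoietic bins rose and 2 fell (9 adjusted over the list alone, 0.07, adjusted p = 0.0429, or 0.151 with an estimated correlation), and 12 of 46 neuronal bins fell and 3 rose (14 adjusted over the list alone, -0.06, adjusted p = 0.0487, or 0.132 with an estimated correlation). Hox clusters had 4 of 9 bins higher (5 adjusted over the list alone, 0.08, adjusted p = 0.0487, or 0.219 with an estimated correlation). Fibroblast bins (adjusted p = 0.206, Thy1 0.18, Pdgfrb 0.15, Col3a1 -0.13) and epithelial bins (adjusted p = 0.0766, Cldn4 0.19, with -0.15 in females at Epcam) did not pass as lists, nor did imprinted genes (0.370), clustered protocadherins (0.101), the first or last 5 Mb of chromosomes (0.571 and 0.225) and the chromosomes with nucleolar organisers (0.911). Of the 685 bins with 5 or more genes, 426 rose and 88 fell (542 adjusted over the list alone, adjusted p = 8.31e-15, or 0.106 with an estimated correlation), and of the bins without a gene midpoint 1436 rose and 4542 fell (5876 adjusted over the list alone, adjusted p = 1.78e-17, and 0.0103 with an estimated correlation). After removal of the trend on enrichment, the medians were -0.0070 for ribosomal protein, 0.03 for break-response, -0.03 for olfactory and -0.03 for vomeronasal bins. They were -0.04 for sirtuin, -0.01 for p53 target, -0.02 for haematopoietic, -0.0012 for zinc finger and 0.00036 for long fragile bins. The direction of these lists and of the ribosomal list thus turned. The median was 0.03 for replication-dependent histone, -0.02 for neuronal and 0.05 for Hox bins, -0.0099 for bins with 5 or more genes and -0.0032 for those without a gene midpoint (157 higher, 160 lower).

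**Figure D1:**
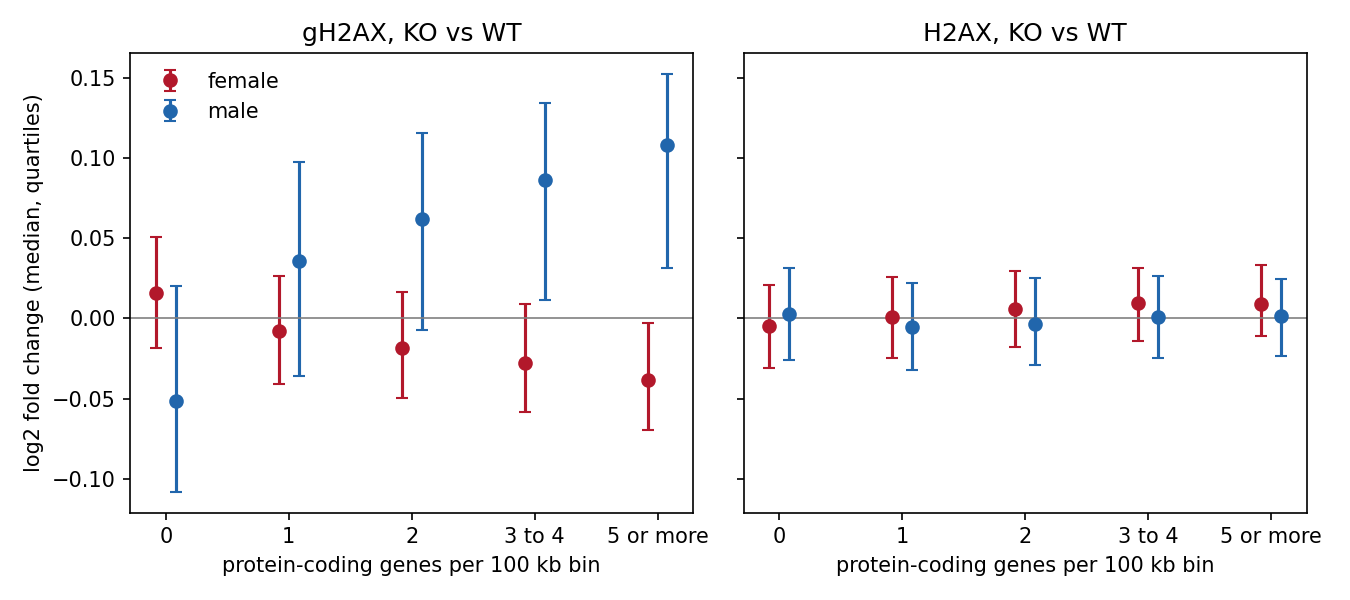
Log2 fold change, KO against WT, of gH2AX (left) and H2AX (right) by the number of protein-coding genes per 100 kb bin, in females (red) and males (blue); points are medians over bins and bars the quartiles. The gH2AX median runs from -0.05 to 0.11 in males and from 0.02 to -0.04 in females as gene number increases, while the H2AX medians stay within 0.01 of 0.

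In females, the gH2AX profile changed in far fewer bins, and several of the largest changes lay where the input had changed too. The largest fall was at 8: 47500001 to 49200000 (17 bins, Tenm3, a teneurin adhesion protein, Wwc2 and Dctd), where the leading bin changed by -1.05 ± 0.04. Falls in regions that were lower in input as well were also seen at 13: 89400001 to 89700000 (-0.38 ± 0.03, Hapln1 and Vcan, which encode proteins of the extracellular matrix) and X: 169900001 to 170100000 (-0.42 ± 0.03, Mid1). At 12: 55100001 to 55300000 (Srp54c, Srp54b, Ppp2r3c) the signal rose by 0.40 ± 0.04. Where input changed by at most 0.10 (log2), gH2AX fell at the bin with Rn18s-rs5 (17: 39800001 to 39900000, -0.68 ± 0.02), at 11: 109000001 to 109100000 (-0.57 ± 0.03) and at 3: 5800001 to 5900000 (-0.54 ± 0.03), and rose at 9: 3000001 to 3100000 (0.20 ± 0.02), 14: 19400001 to 19500000 (0.18 ± 0.02) and 2: 98600001 to 98700000 (0.14 ± 0.02). The bins at 9: 3000001, 14: 19400001 and 2: 98600001 held 1.13%, 1.08% and 5.23% of all reads. Over all groups their gH2AX lay below input (-0.24, -0.30 and -0.34), and in KO males it fell (-0.26, -0.26 and -0.23). Whether reads of repeats gathered there was not tested. In all, 260 of 25702 bins passed (107 higher, 153 lower), with a median size of 0.15. The count was 166 without female KO replicate 1, 75 without female KO replicate 2 and 88 without female WT replicate 1, 97 with DESeq2 (9 higher, 88 lower), 100 with the input change subtracted and 63 after removal of the trend on enrichment.

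The gene lists that passed in both sexes had female medians smaller in size and opposite in sign to those of males, with at most 3 called bins each. The median of ribosomal protein bins was -0.04 (1 of 72 lower, none higher, 1 adjusted over the list alone, adjusted p = 3.47e-06, or 0.155 with an estimated correlation). Olfactory and vomeronasal receptor bins had medians of 0.03 and 0.04 without a called bin (0 adjusted over the list alone, adjusted p = 3.17e-04 and 3.40e-05, or 0.119 and 0.146 with an estimated correlation). Long fragile genes had a median of 0.03 with 3 of 314 bins higher (3 adjusted over the list alone, adjusted p = 0.00196, or 0.209 with an estimated correlation). Fibroblast bins had a median of -0.05 with 1 of 23 lower (1 adjusted over the list alone, adjusted p = 0.00196, or 0.131 with an estimated correlation), the bin of Fn1, which encodes fibronectin (-0.14). The break-response, p53 target, zinc finger and haematopoietic lists passed downwards as well (adjusted p = 0.0389, 0.0323, 0.00433 and 0.0127), with 0, 0, 3 and 1 called bins (0, 0, 4 and 1 adjusted over the list alone), and had adjusted p = 0.165, 0.165, 0.147 and 0.155 with an estimated correlation. The X-linked multicopy list passed upwards (median 0.03, no called bin, 0 adjusted over the list alone, adjusted p = 0.0127, or 0.181 with an estimated correlation). All X bins had a median of 0.03 as well. The multicopy list also holds Slx4 and Slx1b, DNA repair genes on autosomes that matched its name pattern. Of the gene lists, none passed in females with an estimated correlation. After removal of the trend on enrichment, the female medians were 0.00029 for ribosomal protein, 0.0087 for break-response and 0.0042 for zinc finger bins, which turned their direction. They were 0.0050 for olfactory, 0.0077 for vomeronasal, 0.0089 for long fragile, -0.0017 for p53 target, -0.02 for haematopoietic, -0.03 for fibroblast and 0.03 for X-linked multicopy bins.

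Whether the difference in gH2AX between KO and WT depended on sex was tested by the interaction of genotype and sex. At the bin with Rn18s-rs5 (17: 39800001 to 39900000) gH2AX was 2190 ± 127 CPM in KO and 3515 ± 261 in WT females (SD, n = 2), against 3716 ± 150 in KO and 2110 ± 72.4 in WT males, so that the fitted KO to WT ratio in females was 0.354 times that in males. Stretches where the change was higher in females than in males included 2: 97600001 to 100300000 (Lrrc4c, 0.38 ± 0.03), 16: 81300001 to 83400000 (Ncam2, 0.38 ± 0.06) and 14: 107100001 to 109700000 (Slitrk1, 0.37 ± 0.06), and those where it was lower included 2: 31400001 to 33500000 (Ralgps1, Garnl3, Abl1, -0.32 ± 0.05), 11: 119000001 to 121000000 (Rptor, Ccdc57, Rnf213, -0.31 ± 0.05) and 4: 148900001 to 151100000 (Rere, Pex14, Kif1b, -0.28 ± 0.05). The value for the Lrrc4c stretch is again that of the bin at 2: 98600001 to 98700000, which held 5.23% of all reads. The interaction passed in 10404 of 25702 bins (5157 higher in females, 5247 lower). It passed in 5950 with the input change subtracted and in 248 after removal of the trend on enrichment. Across 24032 autosomal bins, which are not independent replicates, the female and male changes correlated with r = -0.51 and rho = -0.56 (r = -0.03 after removal of the trend), and of 172 autosomal bins called in both sexes (115 expected by chance) 164 went in opposite directions. For H2AX and input the same r was -0.02 and -0.05.

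**Figure D2:**
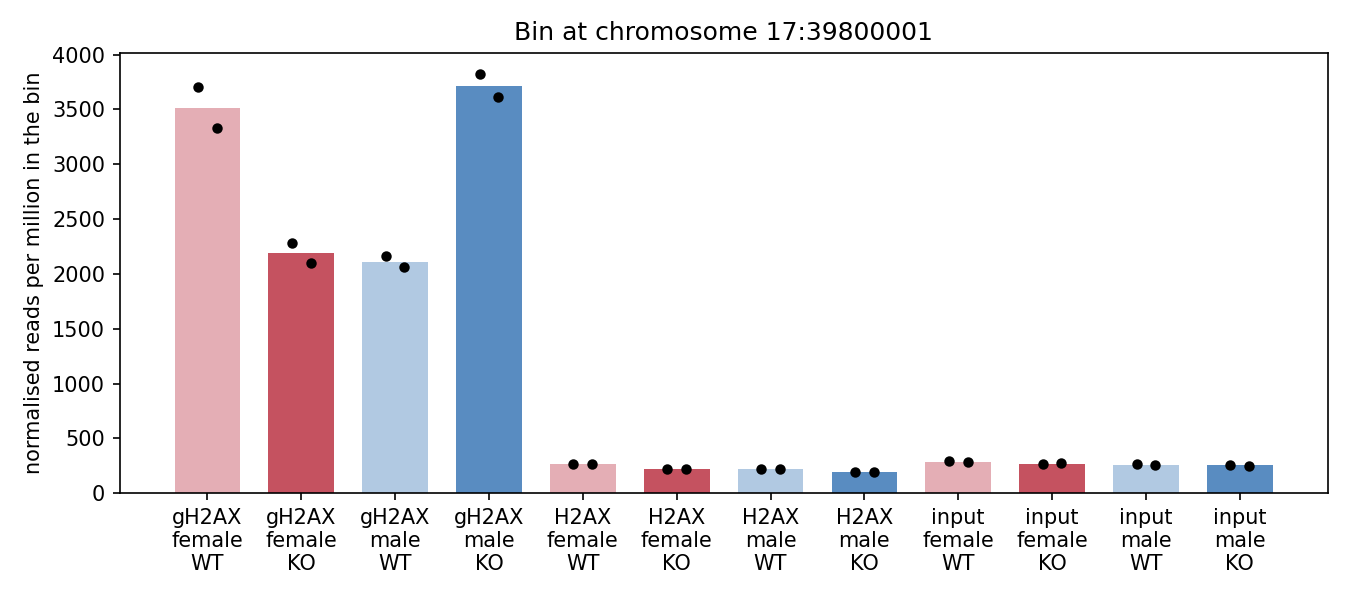
Normalised CPM in the bin at 17: 39800001 to 39900000, which holds Rn18s-rs5, for each of the 12 groups; bars are means and dots the 2 libraries, with females in red, males in blue and KO in the darker shade. gH2AX was lower in female KO (2190) than female WT (3515) and higher in male KO (3716) than male WT (2110), while H2AX and input stayed between 197 and 290.

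Averaged over the sexes, 1006 bins differed for gH2AX (673 higher, 333 lower). Among the regions that fell, those with the most bins also had an input change. Regions that rose included 16: 10600001 to 10900000 (Clec16a, Rmi2 and Socs1, a suppressor of cytokine signalling, 0.13 ± 0.02) and 17: 13500001 to 13800000 (Tcte2, Afdn, 0.17 ± 0.03), where the male changes were 0.25 and 0.32 and the female changes 0.01 and 0.0089. At 6: 34600001 to 34800000 (Agbl3 and Cald1, which encodes caldesmon) the signal fell by 0.13 (log2), with -0.09 in females and -0.16 in males. Leaving out female KO replicate 1 gave 262 bins, female WT replicate 2 391, male KO replicate 1 206, male KO replicate 2 605 and male WT replicate 2 213, and DESeq2 gave 536 (518 higher, 18 lower). Subtraction of the input change gave 10 bins and removal of the trend on enrichment 123.

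H2AX itself changed little with genotype. In females, 39 bins passed (8 higher, 31 lower) and in males 49 (27 higher, 22 lower), and of these 33 and 29 were also called in input, all in the same direction. In females the regions were 8: 47500001 to 49100000 (Tenm3, Wwc2, Dctd, -0.94 ± 0.03), 13: 89400001 to 89700000 (Hapln1, Vcan, -0.46 ± 0.03), X: 169900001 to 170100000 (Mid1, -0.37 ± 0.03) and 12: 55100001 to 55300000 (Srp54c, Srp54b, Ppp2r3c, 0.41 ± 0.04). In males they were 12: 55100001 to 55300000 (-0.83 ± 0.04), 19: 37200001 to 37400000 (0.50 ± 0.03, Ide, insulin-degrading enzyme, Kif11, a mitotic kinesin, and Marchf5), 16: 35400001 to 35600000 (Pdia5, Sema5b, 0.42 ± 0.03), 19: 39200001 to 39400000 (0.48 ± 0.04, cytochrome P450 genes Cyp2c39, Cyp2c29 and Cyp2c38) and 2: 100400001 to 100800000 (-0.41 ± 0.04). At 7: 90400001 to 90500000, the bin with the highest H2AX, the change was -0.36 ± 0.06 in females and 0.61 ± 0.06 in males, with -0.28 and 0.27 in input. H2AX at the bin with Rn18s-rs5 (17: 39800001 to 39900000) was -0.28 ± 0.03 and -0.18 ± 0.03. Of the 46 lists, 4 passed in females. Chromosome 8, which holds the region of Tenm3, was lower (17 of 1263 bins lower, none higher, 21 adjusted over the list alone, adjusted p = 0.00589, and 0.00732 with an estimated correlation). The ribosomal protein list (median 0.02), the bins with 5 or more genes (0.0091, 1 bin higher, 1 adjusted over the list alone) and the X escape list (-0.01) had adjusted p = 0.0423 each, or 0.310 with an estimated correlation. In males the olfactory list alone passed (0.02, adjusted p = 0.0132, or 0.498 with an estimated correlation). The ribosomal, X escape and olfactory lists had 0, 2 and 1 bins adjusted over the list alone, and 0, 1 and 1 over all bins, all lower. The male count was 328 without male KO replicate 1, 26 without male WT replicate 1, 30 without male WT replicate 2 and 31 with DESeq2, and without the bins called in input 4 bins were left in females and 19 in males. With the input change subtracted the counts were 0 and 8.

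Several changes were seen in all 3 kinds of library. At 8: 47500001 to 49200000 in females the leading bin had 18.5 ± 0.498 CPM in KO input against 37.5 ± 0.640 in WT (SD, n = 2), 27.0 ± 0.326 against 51.9 ± 1.29 in H2AX and 22.5 ± 0.828 against 46.5 ± 2.05 in gH2AX. The male groups had 37.6 ± 0.502 and 36.2 ± 0.866 in input. At 12: 55100001 (Srp54c, Srp54b, Ppp2r3c) the changes were 0.39, 0.41 and 0.40 in females and -0.76, -0.83 and -0.72 in males for input, H2AX and gH2AX, and at 19: 37300001 (Ide, Kif11, Marchf5) they were 0.51, 0.50 and 0.61 in males. Input differed between KO and WT in 47 bins in females (13 higher, 34 lower) and 57 in males (25 higher, 32 lower). The female count was 28 within the window on input depth, and the male count was 37 without male WT replicate 1 and 31 with DESeq2.

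**Figure D3:**
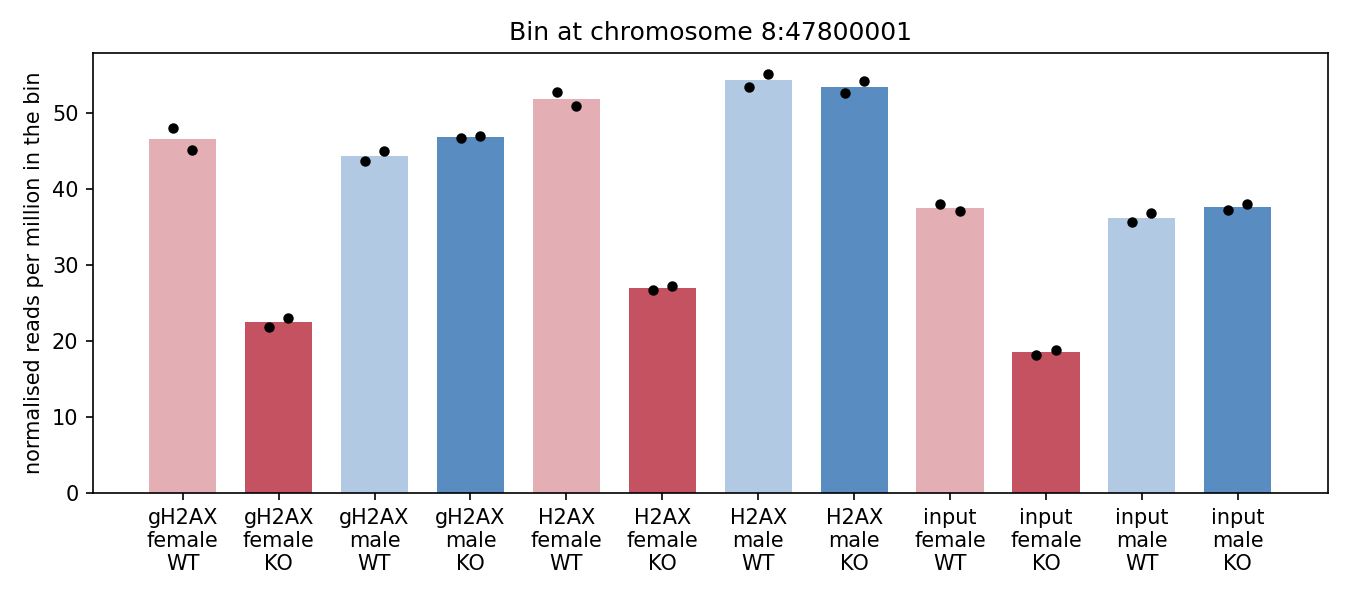
Normalised CPM in the bin at 8: 47800001 for each of the 12 groups; bars are means and dots the 2 libraries, with females in red, males in blue and KO in the darker shade. In female KO the bin had 18.5 in input, 27.0 in H2AX and 22.5 in gH2AX, against 37.5, 51.9 and 46.5 in female WT.

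The series title names the female X chromosome, so the share of reads on X was compared with that on the autosomes. The gH2AX share on X rose by 0.019 ± 0.0040 (log2, 1.34%) in KO females (adjusted p = 0.00373) and fell by 0.033 in KO males (SE 0.0040, -2.27%, adjusted p = 2.39e-04), and the 2 changes differed by 0.052 ± 0.0057 (adjusted p = 1.24e-04). Over all bins, 18 of 20 chromosomes passed in females and 19 in males. The largest changes were on chromosome 17 (-0.066 ± 0.0076 in females, 0.089 ± 0.0076 in males) and chromosome 2 (0.052 ± 0.0041 and -0.087 ± 0.0041), X being the 8th and the 7th by size. Within the window on input depth, which leaves out the bins at 17: 39800001 and 2: 98600001, chromosome 17 was at -0.0047 and 0.011 and chromosome 2 at -0.00081 and -0.0033. X then had the largest change of the 20 chromosomes in both sexes (0.032 ± 0.0043 and -0.052 ± 0.0043, adjusted p = 9.23e-04 and 6.38e-05) and in the interaction (0.084 ± 0.0061), followed by chromosome 8 in females (-0.019) and chromosome 11 in males (0.033). Measured as the median of bins, the X shift was 0.032 ± 0.0041 in females and -0.050 ± 0.0041 in males, against autosomal ranges of -0.021 to 0.016 and -0.029 to 0.050. After removal of the trend on enrichment, these shifts were 0.017 ± 0.0037 and -0.041 ± 0.0037. For H2AX the X share fell in females by 0.010 (SE 0.0029, adjusted p = 0.00798) and did not pass in males (0.0028, adjusted p = 0.404), with an interaction of -0.013 (adjusted p = 0.0158). With limma the adjusted p-values of the female change and the interaction were 0.407 and 0.140, and neither passed with the median of bins, within the window on input depth or with the input change subtracted. Leaving out female KO replicate 1, female KO replicate 2 or female WT replicate 2 of H2AX also ended the female call (-0.013, -0.0079 and -0.0066). These 3 libraries, male KO replicate 2 and either male WT replicate also ended that of the interaction (-0.0063 to -0.015). Relative to H2AX, the gH2AX share on X rose by 0.030 ± 0.0062 in females and fell by 0.036 in males (adjusted p = 7.85e-04 and 6.91e-05). In the exact permutation test of 2 against 2 libraries, p was 0.333 for gH2AX in each sex and for female H2AX, the smallest the design allows (0.667 adjusted over 6 tests).

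**Figure D4:**
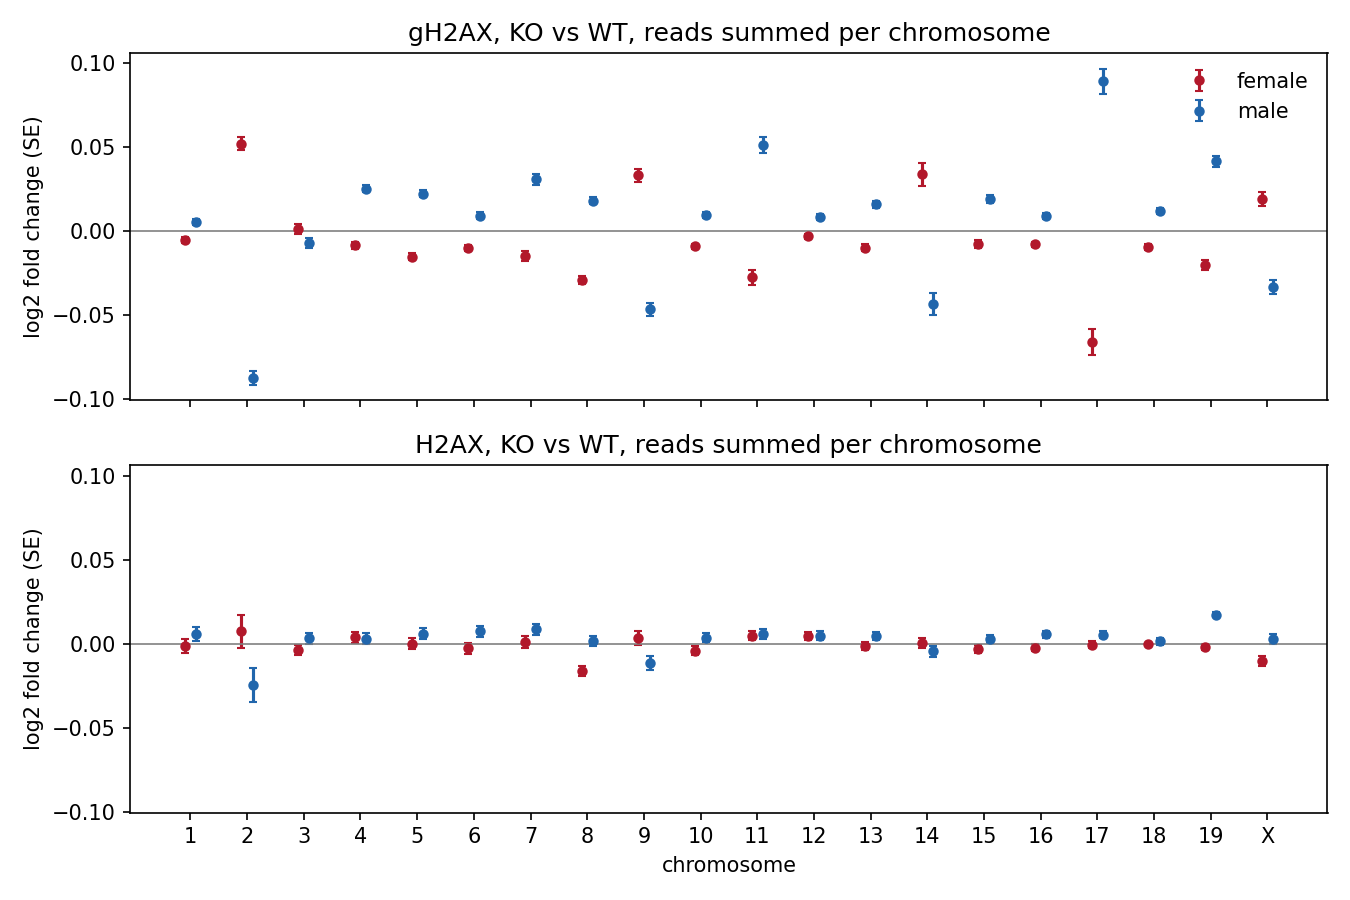
Log2 fold change, KO against WT, of reads summed per chromosome relative to the autosomal total, for gH2AX (top) and H2AX (bottom), in females (red) and males (blue), with SE bars. For gH2AX, chromosome 17 lies at -0.066 in females and 0.089 in males, chromosome 2 at 0.052 and -0.087 and chromosome X at 0.019 and -0.033, while H2AX lies between -0.025 and 0.017. All bins are summed; within the window on input depth the gH2AX values are -0.0047 and 0.011 on chromosome 17, -0.00081 and -0.0033 on chromosome 2 and 0.032 and -0.052 on chromosome X.

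Of the lists of X-linked genes, the multicopy list passed in gH2AX KO against WT in females (median 0.031, adjusted p = 0.0127, or 0.181 with an estimated correlation), and no other passed in either sex. The lists were compared with all other bins. All X bins had a female median of 0.028, so the pass does not set the multicopy list apart from the rest of X. The X inactivation centre (8 bins) had medians of -0.0039 in females and 0.03 in males (adjusted p = 0.991 and 0.525), with 0 and 1 called bins, also 0 and 1 adjusted over the list alone. The bin of Xist, the RNA that coats the inactive X, and its antisense Tsix (X: 103400001 to 103500000) changed by -0.0092 ± 0.04 and 0.06 ± 0.04 (adjusted p = 0.942 and 0.236). Ftx, a non-coding activator of Xist, changed by 0.16 ± 0.04 in males (adjusted p = 7.84e-04) and 0.0054 ± 0.04 in females. X escape genes (15 bins) had adjusted p = 0.945 and 0.895 with 1 lower bin in each sex (1 and 0 adjusted over the list alone), and Kdm6a, a histone demethylase that escapes inactivation, changed by 0.03 and -0.12 (adjusted p = 0.747 and 0.0236). X-linked genes subject to inactivation (34 bins) had adjusted p = 0.668 and 0.524 with 0 and 7 called bins (0 and 4 adjusted over the list alone). Of the inactive-X structural loci, which had adjusted p = 0.798 and 0.368 with 0 and 1 called bins (the same numbers adjusted over the list alone), Firre changed by 0.0055 and 0.08 (adjusted p = 0.963 and 0.0839) and Dxz4 (4933407K13Rik) by -0.04 and 0.10 (0.582 and 0.0274). The X-linked multicopy list did not pass in males (-0.04, adjusted p = 0.324, 6 bins higher and 16 lower, 17 adjusted over the list alone). Over all of X, 94 of 1670 bins were higher and 367 lower in KO males, and 7 and 2 in KO females. Removal of the trend on enrichment turned the medians of the X inactivation centre to 0.01 in females and -0.02 in males. In males it also turned those of X escape genes from 0.02 to -0.02, of genes subject to inactivation from 0.02 to -0.03 and of the inactive-X structural loci from 0.08 to -0.03 (in females from -0.0052 to 0.02). The Ftx, Kdm6a and Dxz4 values in males lost their calls after removal of the trend on enrichment (0.03, -0.11 and -0.06).

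gH2AX was also set against H2AX, which removes changes shared by the 2 marks. A difference in gH2AX pull-down strength between the groups stays in this ratio, and the trend on enrichment was not removed from it. In KO males 7747 bins differed (4081 higher, 3666 lower) and in KO females 61 (25 higher, 36 lower), and 7310 differed between the sexes (3434 higher and 3876 lower in females). In females the ratio fell at 16: 11100001 to 11200000 (Zc3h7a, Txndc11, Rsl1d1, -0.54 ± 0.05), 9: 123400001 to 123500000 (Lars2, Limd1, -0.53 ± 0.04), 16: 57300001 to 57400000 (Cmss1, Filip1l, Tmem30c, -0.50 ± 0.04) and 5: 146200001 to 146300000 (Cdk8, Rnf6, -0.47 ± 0.04), all among the 8 bins highest in gH2AX. Whether reads of repeats gathered in these bins was not tested. In males the ratio rose at 19: 3300001 to 4500000 (Ppp6r3, Lrp5, Kdm2a, 0.28 ± 0.05) and 1: 134900001 to 136300000 (Nav1, Lgr6, Igfn1, 0.23 ± 0.05). Without the 3 libraries of 1 replicate number, the female count was 22 (KO replicate 2) or 35 (WT replicate 1), the male count 4478 (KO replicate 2), 4623 (WT replicate 1) or 3786 (WT replicate 2), and the count between sexes 4309 (female KO replicate 2) or 4830 (male WT replicate 2). DESeq2 gave 193 bins in females (4 higher, 189 lower).

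Female and male cells were compared to place X dosage. In input, the X share was higher in females by 0.86 ± 0.0016 (log2), and 1667 of 1670 X bins passed for each of input, H2AX and gH2AX. Relative to input, the X share of H2AX and gH2AX was higher in females than males by 0.044 ± 0.0044 and 0.040 ± 0.0044 (adjusted p = 4.03e-07 and 1.65e-06), the largest change of the 20 chromosomes for both. Averaged over groups, the X share differed from input by -0.026 ± 0.0022 for gH2AX and -0.052 ± 0.0022 for H2AX, and within the window on input depth by -0.059 ± 0.0019 and -0.10 ± 0.0019. The groups differed for gH2AX: the ratio to input was 0.0048 ± 0.0044 in female KO (adjusted p = 0.303), -0.017 in female WT, -0.061 in male KO and -0.030 in male WT. Within the window it was -0.019, -0.054, -0.11 and -0.056 in that order, so that relative to input the sexes lay close together in WT and apart in KO. The H2AX ratio to input within the window was -0.085, -0.080, -0.12 and -0.12 in the same order, apart between the sexes in both genotypes. Set against H2AX instead of input, gH2AX on X would thus differ between the sexes in WT as well. Off X, 412 of 24032 autosomal bins differed between the sexes for gH2AX, among them 8: 47500001 to 49200000 (Tenm3, -0.53 ± 0.03) and 2: 100400001 to 100900000 (0.30 ± 0.03), where input had changed with genotype in a single sex. Totals were 2079 bins for gH2AX (1855 higher, 224 lower), 2605 for H2AX (2158 higher, 447 lower) and 1838 for input (1765 higher, 73 lower). With the input difference subtracted, 6 bins were left for gH2AX and 135 for H2AX.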

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

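The test for swapped labels was chosen after the result was seen, as was removal of the trend on enrichment as an alternative, while the values that removal would need to give were written down before it was run. A total of 5 results were singled out because the KO effect differed between the sexes in a test of the interaction: gH2AX in 10404 bins, H2AX in 70 bins, gH2AX over H2AX in 7310 bins, and the share on chromosome X of gH2AX (0.0524, log2) and of H2AX (-0.0131).

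The gH2AX changes between KO and WT were negatively correlated between females and males, with r = -0.51 and rho = -0.56 across 24032 autosomal bins. In the 685 bins with 5 or more genes the median was 0.11 in males (426 higher, 88 lower) and -0.04 in females (1 higher, 7 lower). Unequal depth was argued against by 10246 male calls (11481 before) with the 8 libraries thinned to the smallest, and swapped genotype labels in one sex by the bin next to that of Sirt7, higher in KO input of both sexes and in gH2AX libraries labelled KO by at least 0.698. Pull-down strength that differed between the 4 groups had the values it needed: after removal of each library's trend on enrichment 583 male bins were called, r between the sexes was -0.03, the SD of male changes over autosomal bins went from 0.10 to 0.05, and the median of the tenth of bins highest in enrichment went from 0.14 to 0.00031. The bin with Rn18s-rs5 (17: 39800001 to 39900000), where reads of many ribosomal repeats can gather, went from -0.68 ± 0.02 to -0.59 ± 0.02 in females and from 0.82 ± 0.02 to 0.60 ± 0.02 in males and stayed called in both. The trend was held level at the extremes of enrichment, and this bin had the highest gH2AX ratio to input. Its correction was thus that of less enriched bins, so the calls kept there do not bear on pull-down strength. Because the removal would also take away a true difference over gene-rich chromatin, and no spike-in is stated in the labels, an effect of SIRT7 loss on gH2AX that differs between the sexes stays open.

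The gH2AX share on chromosome X rose in KO females and fell in KO males. As the median of bins, the female shift went from 0.032 ± 0.0041 to 0.0172 (SE 0.0037) on removal of the trend, against an autosomal range of -0.012 to 0.0088 (adjusted p = 0.0151). The male shift went from -0.050 to -0.041 ± 0.0037, against -0.020 to 0.020 (adjusted p = 2.75e-05). Both shifts thus stayed outside the autosomal range. The trend was fitted on autosomal bins alone, so its removal narrows the autosomal range but need not narrow the X shift as much. Whether differing pull-down strength was the whole cause was therefore not decided. A response of X to enrichment unlike that of autosomes and a difference by sex stay open and were not tested, and 2 libraries per group allow no exact p below 0.333.

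The H2AX interaction count was 237 without H2AX male KO replicate 1, and in 25 bins outside those called in input the interaction passed. The count for gH2AX over H2AX was 4309 without female KO replicate 2 and 4830 without male WT replicate 2. The H2AX interaction on X lost its call without female KO replicate 1 (-0.015), female KO replicate 2 (-0.011), female WT replicate 2 (-0.0094), male KO replicate 2 (-0.0063), male WT replicate 1 (-0.013) or male WT replicate 2 (-0.014).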

How the results depend on the processing

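Removal of the trend on enrichment, leaving out bins called in input and the dispersion estimated by edgeR were chosen only after the results had been seen, and the cause was not tested for any change given here. RLE factors, TMM with X, no filter on low counts (19 results each), the replicate block (30, with 0.0193 for the female gH2AX share on X), the joint fit (13), the fit of 2 antibodies alone (6) and the estimated dispersion (11) left each count within 1.5 times and each chromosome X result on its side of the threshold. The window on input depth gave 28 bins for input in females, called gH2AX values on chromosome X of 0.032 in females, -0.052 in males and 0.084 for the interaction, and values there for H2AX of -0.0077 in females and -0.0061 for the interaction, neither called. With the input change subtracted, gH2AX gave 100 bins in females, 5027 in males, 5950 for the interaction, 10 over both sexes and 6 for female against male. H2AX then gave 0 (edgeR, 1266 at an unadjusted p under 0.05), 8, 5, 1 and 135 in that order, and chromosome X -0.0080 in females and -0.012 for the interaction, neither called. DESeq2 gave 97 (gH2AX, females), 536 (gH2AX, both sexes), 31 (H2AX, males), 46 (H2AX, interaction), 31 (input, males) and 193 (gH2AX over H2AX, females). On chromosome X, H2AX lost its call in females and for the interaction with limma (-0.010 and -0.013) and with the median of bins (-0.0051 and -0.0018). Removal of the trend on enrichment gave 63, 583, 248 and 123 bins for gH2AX in females, in males, for the interaction and over both sexes. Without the bins called in input, H2AX gave 4, 19, 25 and 4 in that order.

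Leaving out 1 library gave, for gH2AX, 75 (without female KO replicate 2; 166 without KO replicate 1, 88 without WT replicate 1) to 324 bins in females, 7000 (without male WT replicate 2; 7510 without KO replicate 2) to 8325 in males and 206 (without male KO replicate 1; 262, 391, 605 and 213 without female KO replicate 1, female WT replicate 2, male KO replicate 2 and male WT replicate 2) to 1084 over both sexes. For H2AX it gave 26 to 328 in males (26, 30 and 328 without WT replicate 1, WT replicate 2 and KO replicate 1) and, without male KO replicate 1, 237 for the interaction (lowest 51) and 120 over both sexes (lowest 32). Input in males gave 37 (without WT replicate 1) to 69. gH2AX over H2AX gave 22 (without KO replicate 2; 35 without WT replicate 1) to 57 in females, 3786 (without WT replicate 2; 4478 and 4623 without KO replicate 2 and WT replicate 1) to 5776 in males and 4309 (without female KO replicate 2; 4830 without male WT replicate 2) to 6490 for the interaction. The H2AX share on X ranged from -0.014 to -0.0066 in females (call lost without KO replicate 1, KO replicate 2 or WT replicate 2) and from -0.020 to -0.0063 for the interaction (call kept without female WT replicate 1 or male KO replicate 1 alone).

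Of the bins that led a region or held a named gene, 158 kept direction and call with RLE factors, TMM with X, no filter and the replicate block, and 132 with DESeq2, where 26 lost the call. The input subtraction left 74 of 142, with 58 no longer called, 1 newly called and 9 reversed: for gH2AX in females 11: 120500001 (-0.091) and 13: 89500001 (0.035), over both sexes 13: 89500001 (0.010) and X: 170000001 (0.013), for H2AX in females 3: 94700001 (-0.0030), 8: 47800001 (0.080) and 8: 74000001 (0.039), and in males 19: 37300001 (-0.011) and 11: 120500001 (-0.039). Removal of the trend left 61 of 113, with 45 no longer called, 1 newly called and 6 reversed in males: the bins of Sirt7 (-0.035), Sirt6 (-0.029), Epcam (-0.012), Sirt4 (-0.0114), Sirt2 (-0.0109) and 4933407K13Rik (-0.063). On leaving out 1 library, 687 comparisons of such a bin kept direction and call, 72 lost the call, 1 gained it and 0 reversed. Small changes were found in part: in simulated counts, changes of 1.1-fold were called in 54% of bins for gH2AX in females.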

Other observations

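The dosage tests and the splits within each sex were chosen after the result was seen, and the counts over the other splits of the libraries were planned. Several regions changed in input with genotype, such as 8: 47500001 to 49200000 in females, where the leading bin changed by -1.02, -0.94 and -1.05 (log2) in input, H2AX and gH2AX. DNA dosage that differed between the cultures would give all 3 kinds of library the same change. Over the 17 bins of this region the ratio of the H2AX to the input change had a median of 0.989 (0.51 to 1.2), the value this explanation needs, where a change of input alone would have given 0. Over the 47 female and 57 male calls in input (104 in all, with bins called in both sexes counted once per sex), the median difference between the H2AX and input changes was 0.0744, which decides nothing, since the input change itself had a median size of 0.172. Both libraries of a group shared the change at 8: 47800001, with 18.2 and 18.9 CPM in female KO input against 38.0 and 37.1 in female WT input. Whether a gain or loss of DNA arose in the cultures or was carried by the animals was not tested.

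At the 4 bins with the most H2AX over input, the log2 changes with genotype had opposite signs in the sexes, and those of input had the same signs as those of H2AX. At 7: 90400001 (Dlg2, Sytl2, Tmem126b), 14: 45800001, 10: 121700001 (Srgap1) and 5: 104000001 (Hsd17b11, Sparcl1, Nudt9) the H2AX changes were -0.36, -0.33, -0.30 and -0.27 in females and 0.61, 0.57, 0.48 and 0.45 in males, and those of input -0.28, -0.20, -0.16 and -0.17 and 0.27, 0.23, 0.16 and 0.13. Of the 8 bins highest in H2AX over input these 4 had male H2AX changes that exceeded the input change, by 0.31 to 0.34 (SE 0.056 to 0.063, adjusted p at most 0.00207). DNA dosage alone, changed evenly over a whole bin, was argued against there. A dosage change of only a part of the bin that is rich in H2AX would change H2AX more than input. That form was not tested, so DNA dosage stays open. In females the difference between the H2AX and input changes passed in none of the 8. The bin at 2: 98600001 took 5.27% of gH2AX reads in female KO, 4.80% in female WT, 4.40% in male KO and 5.14% in male WT.

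Relative to H2AX, gH2AX was higher in 12 of 15 bins of X escape genes and lower in none (12 adjusted over the list alone, median 0.13, adjusted p = 0.0164, and 0.0341 with an estimated correlation). Over all of X, 818 of 1670 bins were higher and 341 lower, with a median of 0.043. The list was compared with all other bins and not with the rest of X. The ratio of gH2AX to H2AX was lower in 8 of 10 bins of clustered protocadherins (8 adjusted over the list alone, -0.20, adjusted p = 0.00101, and 0.0192) and in 18 of 30 bins of imprinted genes, with 5 higher (23 adjusted over the list alone, -0.08, adjusted p = 0.0327, and 0.0325).

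Other splits of the same libraries were counted. For KO against WT over both sexes, models of 2 group means without sex gave as many gH2AX bins as the real split in 3 of 35 splits (1, highest other 1707) and as many H2AX bins in 2 of 35 (1, highest other 2321), so chance was not excluded. The highest split was that of females against males in both, a structure of sex, and these models found 1 bin where the reported ones, with sex, found 1006 and 38. With sex in the model and splits made within each sex, 5 of 18 splits gave as many gH2AX bins (1006, highest other 10404) and 2 of 18 as many H2AX bins (38, highest other 70), and 18 splits are too few for a share under 0.05. The highest of these was the split of female KO and male WT against the rest, which is the interaction. With models of 2 group means, 1 of 35 splits for female against male, the real one, gave as many bins for gH2AX (1707, highest other 655), H2AX (2321, highest other 1) and input (1781, highest other 1). X dosage largely fixed this in advance, since 1667 of 1670 X bins passed for each in the main fits, and autosomal bins were not counted apart. Only the real split gave as many bins for gH2AX over input (1 of 30 splits, real 20417, highest other 0), H2AX over input (1 of 30, real 21303, highest other 0) and gH2AX over H2AX (1 of 30, real 15517, highest other 0). Every other split mixed the 2 kinds of library, which widens the spread, so these counts show only that the kinds differ.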
